A study of Mus musculus with 6 samples.

How the data were processed

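Total RNA from untreated and treated cells of a mouse macrophage line was hybridised on 6 two-colour arrays, per the labels. Treated cells had received LPS at 100 ng/ml and LBP at 100 pM, and both were harvested after 4 h. The labels number the arrays as sets 1 to 3 in each of 2 dye orientations, and they call the Cy3 RNA the control and the Cy5 RNA the test on every array. They do not say that both arrays of a set carried the same RNA. Reading each set as a dye swap of 1 pair of RNA samples, counted as 1 replicate, is therefore an assumption.

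The deposited values are log2 ratios, 1 per probe and array, in a value table of 16281 probes. The log base follows from the largest value, 6.643856, which is log2 of a ratio of 100. Every array has a deposited median of 0. The scanner, the feature extraction, the background correction, the normalization and any genome build were not given in the sources used here, so how far the ratios of dim spots were compressed is unknown. The ratio was read as Cy5 over Cy3 because the labels name Cy5 the test channel. As deposited, arrays of opposite orientation correlated below 0 across probes, from -0.775 to -0.397, so the arrays with treated RNA in Cy3 were sign-turned. That the table divides the test by the control channel stays an assumption, and a reversed convention would turn every sign. All 37 measured interferon-stimulated genes and 15 of 21 cytokine genes would then have fallen after LPS, and 0 risen. Both lists were picked from known responders, so their values argue against a reversed convention.

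Between 1254 and 2086 values per array were exactly 0, 902 probes were 0 on all 6 arrays and 1964 on some. Some probes at exactly 0 on 1 array had large ratios on others, so exact zeros were taken as not measured. The 13415 probes with a value on all 6 arrays were kept. Gene names came from the platform's annotation table, in which 13738 probes had 1 gene symbol, 52 had several and 2491 had none listed. Symbols were checked by Entrez Gene ID against the mouse gene table of GRCm38.p6. Of the single-gene probes 13694 matched, 44 did not, and 0 symbols changed. Probes of 1 gene were averaged, and probes with several symbols or none were kept as single unnamed features, which gave 11364 features. Of 1866 genes with several probes, 20 had probes called in opposite directions. Among the genes reported, probes differed by over 2-fold for Fabp4 (0.11 and 2.20), Ifit3 (2.98 and 4.87), Nfkbiz (0.97 and 2.48) and Tap1 (1.27 and 2.43), and those of Cd22 (-0.21 and 0.52) were called in opposite directions. Probes of Ccnd1 (-0.10 and 0.011) and Gapdh (-0.060 to 0.12 over 10) also had both signs, with none called. No coordinates are given, since the table names no build.

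For each set, the mean of the array with treated RNA in Cy5 and the sign-turned array with treated RNA in Cy3 was taken, in which a gene's dye effect cancels. The 3 set values were tested against 0 with limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and an adjusted p below 0.05 as the threshold. The same test on the unturned means, in which the treatment cancels, gave the dye effect. The 35 gene lists (27 of responses and 8 of markers of other cell types), with at least 5 measured genes each, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Calls "adjusted over the list alone" adjust the limma p-values of a list's members among themselves. Array values were also compared by Pearson correlation across genes.

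The design, the lists, most alternatives and the rule for the genes to be named were fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls among called genes with 1 symbol that moved the same way on all 6 arrays. It added for each list up to 4 called and up to 2 uncalled members with the largest absolute change, and, whatever their values, Tnf, Il1b, Il6, Nos2, Ptgs2, Cd14, Tlr4, Lbp, Nfkbia, Cxcl10, Ccl2, Actb and Gapdh. Alternatives covered median centring, scale and quantile normalization, the set number as no, random or fixed block, each dye orientation alone, each set left out, features measured in at least 2 sets, single probes, robust variances, other thresholds, and for lists fry, ranks and an estimated correlation. Keeping exact zeros, using named genes alone, the dye test without set numbers and the estimated correlation over 6 arrays were added after the data were seen. The table holds no intensity to filter dim probes on, so the filter kept genes whose orientations had the same sign in every set.

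The gene test was tested on simulated data with 11364 features, of which 200 were changed, in 10 runs. It recovered 98.8% of 1.5-fold changes and 100% of 2-fold, 4-fold and 8-fold changes, and 4.55% of its calls were false. The list test recovered 100% of lists shifted by 0.5 and called 0% of the others. Both simulations drew independent noise for each gene, with variances from limma's own fit, and left all other genes unchanged. In the real lists the estimated correlation between genes reached 0.268, so these rates need not hold for the real data. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.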

Results

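RNA from RAW 264.7 cells (written RAW 264.4 in part of the labels), a mouse macrophage line grown from a virus-induced tumour, was compared with and without 4 h of treatment with bacterial lipopolysaccharide (LPS, 100 ng/ml) and LPS-binding protein (LBP, 100 pM). LPS is the endotoxin of Gram-negative bacteria, and LBP is the serum protein that hands LPS to its receptor complex of CD14 and TLR4. Each of the 6 arrays carried treated and untreated total RNA in different dyes, and the labels number the arrays as sets 1 to 3 in each dye orientation. Treated RNA was labelled with Cy5 on 3 arrays and with Cy3 on the other 3. Of the 16281 probes, 14195 to 15027 per array held a value other than exactly 0. The number of arrays limits the precision, and the value table used here gives no intensities.

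The series addressed the effect of LPS and LBP on the RNA of these cells after 4 h. All 37 measured genes of the interferon-stimulated list rose. So did 15 of 21 genes of the cytokine list and 11 of 17 of the chemokine list, in which 1 fell. By contrast, 29 of 35 genes of the G1/S transition and DNA replication (1 rose) and 27 of 31 of G2 and mitosis fell. Each of these lists was called as shifted. None was with an estimated correlation (camera adjusted p from 0.153 to 0.253), a version of the test that takes its degrees of freedom from 3 values. Values are log2 ratios of treated over untreated RNA, given as the mean ± SD of n = 3 sets. The direction is the likely one and rests on the labels, which name Cy5 the test and Cy3 the control channel. With the ratio reversed, all 37 interferon-stimulated genes would have fallen after LPS, which argues against that reading. Among named genes measured on all 6 arrays, the largest rise was that of Ifi202b, an interferon-activated gene of a DNA-binding protein family, at 4.79 ± 0.11 (27.6-fold). Rsad2, an antiviral enzyme gene, rose by 4.36 ± 0.25, and Il1b, the gene of the fever-inducing cytokine interleukin-1β, by 4.17 ± 0.055. Id2, an inhibitor of helix-loop-helix transcription factors, had the largest fall at -2.07 ± 0.18. Cxcl2, a neutrophil attractant gene named after its value was seen, was measured in only 2 sets and rose by 4.82 ± 0.37 there.

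The other 9 of the 12 largest rises of named genes measured on all 6 arrays lay between 3.85 and 4.04. They were the chemokine genes Ccl2 (4.04 ± 0.24) and Cxcl10 (3.98 ± 0.30), the interferon-induced Ifit2 (4.01 ± 0.081), Ifit1 (4.00 ± 0.091) and Ifit3 (3.92 ± 0.094), interferon-β itself (Ifnb1, 3.94 ± 0.65), the predicted gene Gm9706 (3.87 ± 0.26), the acute-phase gene Saa3 (3.85 ± 0.12) and the ubiquitin-like modifier gene Isg15 (3.85 ± 0.47). Falls were smaller. After Id2 came Cytip (-1.69 ± 0.036), a regulator of leukocyte adhesion, Myadml2 (-1.30 ± 0.31), the kinesin gene Kifc3 (-1.25 ± 0.11), the cohesin acetyltransferase gene Esco2 (-1.23 ± 0.16) and the transcription factor gene Pax6 (-1.21 ± 0.10). The thymidine kinase gene Tk1 (-1.12 ± 0.076), the replication licensing inhibitor gene Gmnn (-1.12 ± 0.16), the phosphatase gene Dusp14 (-1.07 ± 0.33), the signalling inhibitor gene Smad6 (-1.07 ± 0.083), Gask1b (-1.04 ± 0.15) and the histone deacetylase gene Hdac9 (-1.02 ± 0.083) completed the 12 largest falls. These 24 genes were taken from called genes that moved the same way on all 6 arrays, and their limma adjusted p ran from 1.59e-08 (Ifi202b) to 3.14e-04 (Dusp14).

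**Figure D1:**
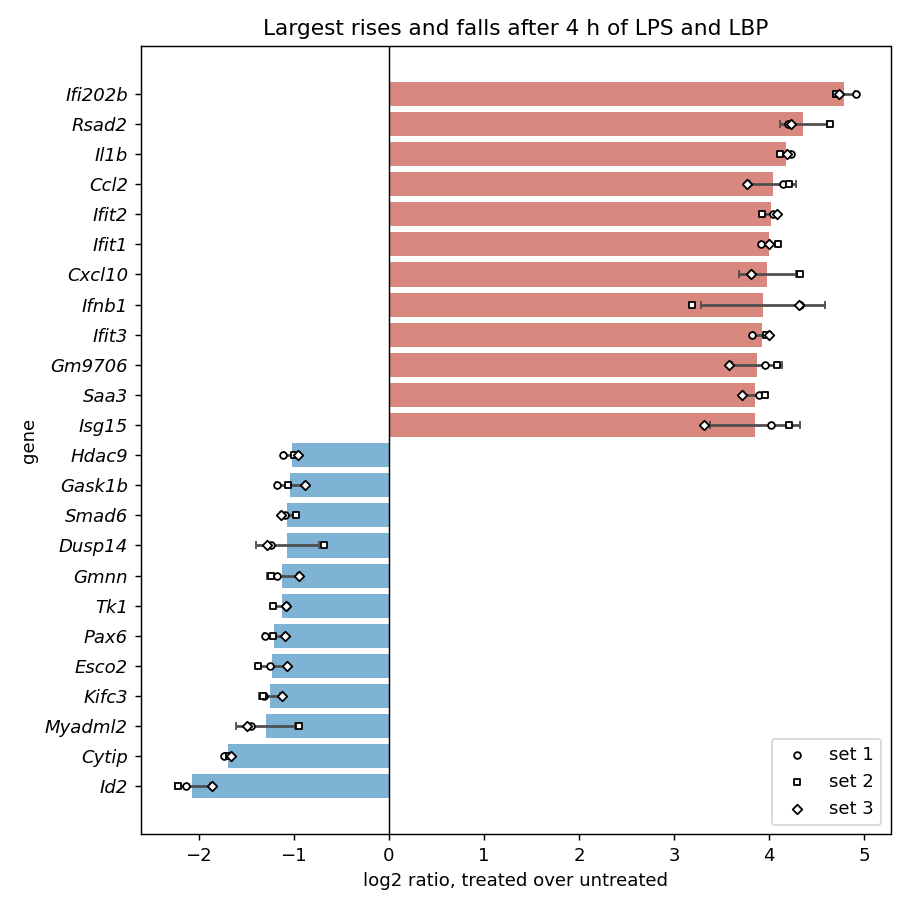
Bars give the mean log2 ratio of treated over untreated RNA for the 12 largest rises and the 12 largest falls among called genes that moved the same way on all 6 arrays, whiskers the SD over n = 3 sets, and points the set values. The rises run from 3.85 (Isg15) to 4.79 (Ifi202b), the falls from -1.02 (Hdac9) to -2.07 (Id2).

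Of 11364 features with values on all 6 arrays (9574 named genes and 1790 other probes), 3294 passed the adjusted threshold, 1586 of them higher and 1708 lower, and 4366 had an unadjusted p below the same level. The median change was 0.31 among those higher and -0.26 among those lower, against a median SD between sets of 0.074. Among named genes, 1333 rose and 1449 fell. At least 2-fold rises numbered 191 and falls 12, while 75 genes rose and 1 fell at least 4-fold. Of the called features, 2523 moved the same way on all 6 arrays and 771 did not. Only 296 features passed a test against a 1.5-fold change, 261 higher and 35 lower. Nothing in the labels says that the sets came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

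Interferon-stimulated genes, the antiviral genes that type I interferon turns on, rose as a group. Of the 37 measured members, all 37 rose, and 37 also did when adjusted over the list alone. Their median change was 2.30, and camera, which compares a list with all other genes, gave adjusted p = 1.21e-36. The call was lost with adjusted p = 0.153 with an estimated correlation. Rsad2, Ifit2, Ifit1 and Ifit3 led the list. For Ifi202b, Isg15, Gm9706 and the Ifit genes, a probe of 1 family member can also bind transcripts of near-identical relatives, so these names are less certain than the changes.

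Inflammatory cytokine genes rose in 15 of 21 measured cases (16 adjusted over the list alone) and fell in 0, with a median of 0.61 (camera adjusted p = 4.81e-11, and adjusted p = 0.224 with an estimated correlation). Besides Il1b and Ifnb1, the granulocyte growth factor gene Csf3 rose by 3.40 ± 0.35, the interleukin-1 receptor antagonist gene Il1rn by 3.16 ± 0.26, Il6 by 2.81 ± 0.46 and Tnf by 2.08 ± 0.18. Csf1, the macrophage growth factor, was at 0.23 ± 0.25 and did not pass (adjusted p = 0.092), although it did without set 2 (0.32, limma adjusted p = 2.92e-04). Of 17 listed chemokine genes, which encode attractants of leukocytes, 11 rose, 1 fell and 5 were not called (11 and 1 adjusted over the list alone). Their median was 0.69 (camera adjusted p = 3.00e-08, and adjusted p = 0.224 with an estimated correlation), and Ccl4 rose by 3.48 ± 0.19 and Ccl7 by 2.82 ± 0.35. The list of NF-κB subunits, inhibitors and targets had 11 rises and 0 falls among 17 members (12 rises adjusted over the list alone) and a median of 0.95 (camera adjusted p = 6.00e-10, and adjusted p = 0.224 with an estimated correlation). Nfkbiz rose by 1.73 ± 0.14, Tnfaip2 by 1.70 ± 0.067, Tnip1 by 1.68 ± 0.071 and Bcl3 by 1.63 ± 0.18, whereas the kinase subunit gene Ikbkg was at 0.075 ± 0.037. Nfkbia, the inhibitor IκBα, was listed at exactly 0 in set 1 and was measured in 2 sets, where it rose by 1.20 ± 0.12 (adjusted p = 3.96e-05 in a limma fit of features measured in at least 2 sets).

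Genes of effector enzymes and proteases rose in 16 of 22 cases and fell in 2 (17 and 2 adjusted over the list alone; camera adjusted p = 7.85e-06, and adjusted p = 0.242 with an estimated correlation). Ptgs2, the inducible prostaglandin synthase, rose by 1.85 ± 0.35. On the treated-in-Cy5 arrays alone it was at 1.47 and missed the threshold (adjusted p = 0.0515). Gch1, which starts the synthesis of the cofactor tetrahydrobiopterin, rose by 1.62 ± 0.15, the urokinase receptor gene Plaur by 1.38 ± 0.11, and Nos2, the inducible nitric oxide synthase, by 0.58 ± 0.14. The class I antigen presentation list had 12 rises, 0 falls and 3 members not called out of 15 (13 rises adjusted over the list alone; camera adjusted p = 1.82e-08, and adjusted p = 0.224 with an estimated correlation). In it, the peptide transporter gene Tap1 rose by 1.85 ± 0.048 and Tapbp by 1.09 ± 0.16. Co-stimulatory and adhesion molecules counted 10 rises and 1 fall among 20 (10 and 1 adjusted over the list alone; camera adjusted p = 1.57e-05, and adjusted p = 0.224 with an estimated correlation). Cd40 rose by 3.48 ± 0.39, the death receptor gene Fas by 3.20 ± 0.24 and Cd83 by 1.88 ± 0.19. In that list 9 genes were not called. The co-stimulatory ligand genes Cd80 (0.057 ± 0.15) and Cd86 (0.073 ± 0.14) did not pass (limma adjusted p = 0.563 and 0.433). Both were named after their values were seen.

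Receptor and signalling genes moved in both directions. In the Toll-like receptor pathway 12 of 23 genes rose and 3 fell (13 and 3 adjusted over the list alone; camera adjusted p = 0.00111, and adjusted p = 0.224 with an estimated correlation). Tlr3, the sensor of double-stranded RNA, rose by 2.12 ± 0.39 and Tlr2 by 1.13 ± 0.052, while Tlr4, the LPS receptor, fell to -0.55 ± 0.076 (adjusted p = 1.27e-04). The co-receptor gene Cd14 was at 0.073 ± 0.071 and did not pass (adjusted p = 0.304). Lbp, the gene of the protein added to the medium, was at -0.096 ± 0.20 (adjusted p = 0.391), and without set 1 it was at -0.20 (limma adjusted p = 0.0417). Feedback inhibitors rose in 12 of 20 cases and fell in 2 (13 and 4 adjusted over the list alone; camera adjusted p = 1.37e-04, and adjusted p = 0.224 with an estimated correlation), among them the RNA-decay factor gene Zfp36 (1.84 ± 0.12), the transcription factor gene Atf3 (1.72 ± 0.063) and the cytokine signalling suppressor gene Socs1 (1.25 ± 0.20). Of 26 immediate early transcription factors, 13 rose and 5 fell (14 and 5 adjusted over the list alone; camera adjusted p = 0.00153, and adjusted p = 0.224 with an estimated correlation), with Myc at 3.00 ± 0.36, Egr1 at 2.25 ± 0.12 and Cebpd at 2.16 ± 0.13. G protein-coupled receptors and their RGS regulators had 15 rises and 3 falls among 37 (15 and 4 adjusted over the list alone; camera adjusted p = 0.00963, and adjusted p = 0.226 with an estimated correlation), among them Rgs16 (2.92 ± 0.22) and the fatty acid receptor gene Gpr84 (1.95 ± 0.10).

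Upward shifts were called in 4 further lists. Actin cytoskeleton genes had 13 rises and 2 falls among 27 (14 and 2 adjusted over the list alone; camera adjusted p = 6.34e-04, and adjusted p = 0.224 with an estimated correlation). In it, Marcksl1 rose by 2.03 ± 0.13 and Vasp, a regulator of actin filament growth, by 0.57 ± 0.085. Actb, the β-actin gene often used as a reference, rose by 0.28 ± 0.17 (adjusted p = 0.0167), a call that ended on either orientation alone, at 0.16 with treated RNA in Cy5 (adjusted p = 0.172) and 0.39 with it in Cy3 (adjusted p = 0.0626), and with exact zeros kept as values (adjusted p = 0.149). Proteasome genes rose in 10 of 31 cases and fell in 0 (12 rises adjusted over the list alone; median 0.11; camera adjusted p = 1.36e-04, and adjusted p = 0.224 with an estimated correlation), with Psmd8 at 0.41 ± 0.036. Apoptosis regulators had 10 rises and 6 falls among 28 (13 and 7 adjusted over the list alone; camera adjusted p = 0.0141, adjusted p = 0.229 with an estimated correlation, and 0.1 on ranks). The members that rose most were inhibitors of cell death, Bcl2a1d (2.45 ± 0.16), Bcl2a1a (2.43 ± 0.17) and Cflar (1.47 ± 0.085). Bcl2a1d and Bcl2a1a are near-identical copies that a probe cannot tell apart with certainty. Other cell death genes went the other way. Bcl2l11, which promotes death, rose by 0.76 ± 0.036, and the inhibitor gene Bcl2 fell to -0.29 ± 0.058 (limma adjusted p = 1.45e-05 and 0.00229). Both were named after their values were seen. The death receptor gene Fas, counted in another list, rose by 3.20 ± 0.24. Macrophage identity and scavenger receptor genes had 11 rises and 3 falls among 28 (11 and 4 adjusted over the list alone; camera adjusted p = 0.0454, and adjusted p = 0.253 with an estimated correlation). The complement receptor gene C3ar1 rose by 2.35 ± 0.093 and the high-affinity antibody receptor gene Fcgr1 by 1.14 ± 0.13. That list's shift was not called without set 3 (adjusted p = 0.0503), on ranks (adjusted p = 0.11) or over the 6 arrays without set numbers (adjusted p = 0.0684).

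Most cell cycle genes fell. Of 35 genes of the G1/S transition and DNA replication, 29 fell, 1 rose and 5 were not called (29 and 1 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 7.14e-12, and adjusted p = 0.253 with an estimated correlation). Tk1, the replication origin factor gene Cdc6 (-0.84 ± 0.13), the nucleotide reductase gene Rrm2 (-0.76 ± 0.15) and the single-strand binding protein gene Rpa2 (-0.74 ± 0.081) had the largest falls in it, and of the 5 not called, Ccnd1 was at -0.045 ± 0.043 and Cdk4 at -0.042 ± 0.098. Among 31 genes of G2 and mitosis, 27 fell, 0 rose and 4 were not called (29 falls adjusted over the list alone), with a median of -0.26 (camera adjusted p = 3.93e-11, and adjusted p = 0.226 with an estimated correlation). Cyclin A2 (Ccna2) was at -0.59 ± 0.083, the proliferation marker gene Mki67 at -0.49 ± 0.076 and the spindle checkpoint gene Mad2l1 at -0.48 ± 0.076. Apart from that of Tk1, the falls in both lists were under 2-fold.

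**Figure D2:**
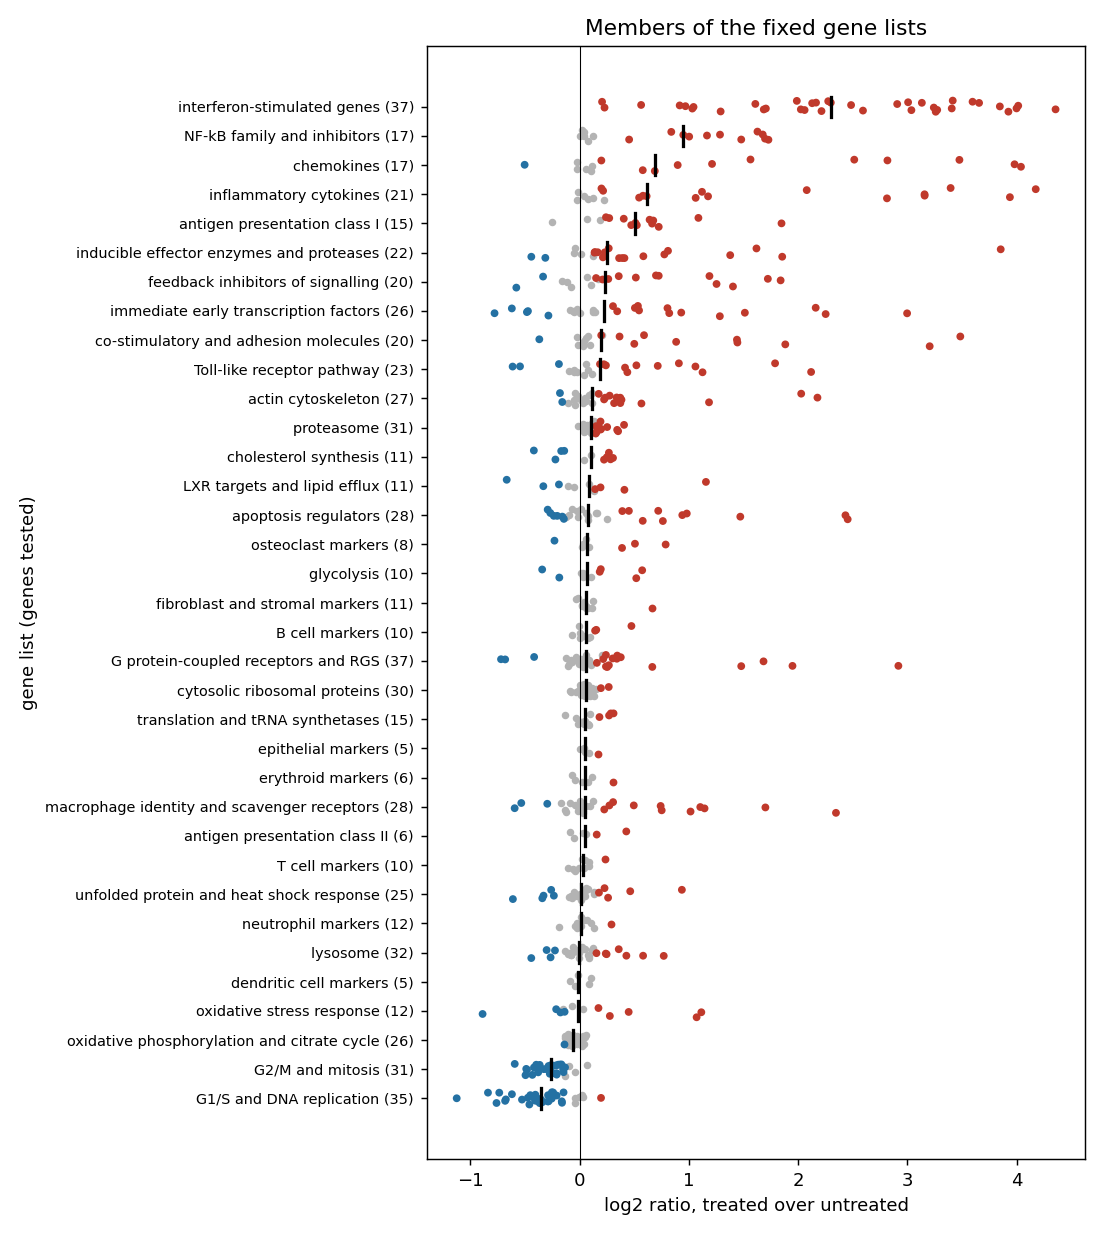
Each point is a measured member of 1 of the 35 lists, placed by its log2 ratio of treated over untreated RNA (mean of n = 3 sets), with called rises in red, called falls in blue and other members in grey. Black bars mark medians, which run from -0.35 (G1/S and DNA replication, 35 genes) to 2.30 (interferon-stimulated genes, 37 genes).

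Several metabolic and housekeeping lists were not called as shifted. In the unfolded protein and heat shock list 5 genes rose and 5 fell of 25 (6 and 5 adjusted over the list alone; camera adjusted p = 0.861), with the stress phosphatase regulator gene Ppp1r15a at 0.94 ± 0.035 and Ddit4 at -0.61 ± 0.032. Oxidative stress genes had 5 rises and 4 falls of 12 (5 and 4 adjusted over the list alone; camera adjusted p = 0.652), among them the metallothionein gene Mt2 at 1.07 ± 0.18 and the glutathione synthesis gene Gclc at -0.89 ± 0.14. In lipid metabolism, LXR targets had 4 rises and 3 falls of 11 (4 and 3 adjusted over the list alone; camera adjusted p = 0.73), with the fatty acid carrier gene Fabp4 at 1.16 ± 0.12 (the mean of probes at 0.11 and 2.20) and the desaturase gene Scd1 at -0.67 ± 0.16, and cholesterol synthesis genes had 5 and 4 of 11 (5 and 4 adjusted over the list alone; camera adjusted p = 0.471). Glycolysis genes had 4 rises and 2 falls of 10 (4 and 2 adjusted over the list alone; camera adjusted p = 0.196): the glucose transporter gene Slc2a1 rose by 0.57 ± 0.037 and Hk2 by 0.52 ± 0.073, and Gapdh was at 0.035 ± 0.035 (adjusted p = 0.61). Lysosomal genes rose in 7 and fell in 4 of 32 cases (7 and 5 adjusted over the list alone; camera adjusted p = 0.62), with the lysozyme gene Lyz2 at 0.77 ± 0.098. Respiration and citrate cycle genes counted 0 rises and 1 fall of 26 (0 and 0 adjusted over the list alone; camera adjusted p = 0.138), and tRNA synthetases and translation factors 4 rises and 0 falls of 15 (4 and 1 adjusted over the list alone; camera adjusted p = 0.117). Cytosolic ribosomal protein genes had 2 rises of 30 (0 adjusted over the list alone; median 0.055; camera adjusted p = 0.0514), and passed after median centring (adjusted p = 0.0496) and on ranks (adjusted p = 0.011), against adjusted p = 0.525 with an estimated correlation. Class II antigen presentation genes had 2 rises of 6 (2 adjusted over the list alone; camera adjusted p = 0.429), and the invariant chain gene Cd74 rose by 0.43 ± 0.044.

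None of the 8 lists of markers of other cell types passed the camera test, with the smallest adjusted p at 0.0736 for osteoclast markers (3 rises and 1 fall of 8, and 3 and 1 adjusted over the list alone). That list passed without set 1 (adjusted p = 0.0485, against adjusted p = 0.482 over all sets with an estimated correlation), and the osteoclast fusion gene Ocstamp rose by 0.79 ± 0.091. B cell markers had 3 rises of 10 (3 adjusted over the list alone; adjusted p = 0.183), including the immunoglobulin gene Ighm at 0.47 ± 0.076. Fibroblast markers had 1 rise of 11, Fap at 0.66 ± 0.15 (1 adjusted over the list alone; adjusted p = 0.183), which ended on the treated-in-Cy5 arrays alone (adjusted p = 0.0645). There was 1 rise each among 12 neutrophil (adjusted p = 0.62), 10 T cell (adjusted p = 0.652), 6 erythroid (adjusted p = 0.513) and 5 epithelial markers (adjusted p = 0.381), with 1 each adjusted over the list alone. They were Elane (0.29 ± 0.13, the mean of probes at 0.040 and 0.53), Cd4 (0.23 ± 0.12), Alas2 (0.30 ± 0.11) and Cldn4 (0.17 ± 0.039), of which Cd4 was not called without set 1 or 3 (limma adjusted p = 0.0829 and 0.0942) and Cldn4 without any of the sets (limma adjusted p from 0.054 to 0.0726). Of the 5 dendritic cell markers, 0 were called (0 adjusted over the list alone; adjusted p = 0.981). For the lysosome, oxidative stress and dendritic cell lists the median lay below 0 (-0.0081, -0.019 and -0.012) while the mean and the camera direction were above 0.

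In all, 17 of the 35 lists were called, 15 upward and 2 downward, by camera with a preset correlation of 0.01. With a correlation estimated from the 3 set values none of the 17 calls held. That version also takes its degrees of freedom from the 3 values instead of the number of genes. Over the called lists the estimates ran from -0.043 (NF-κB) to 0.268 (G1/S). For the interferon-stimulated genes the estimate was 9.94e-05, below the preset 0.01, so correlation between genes does not explain the loss of that call. With the correlation estimated from the 6 arrays without set numbers, 1 held, that of the interferon-stimulated genes (adjusted p = 0.0498).

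The dye comparison asked how far the ratio of a gene depended on which RNA carried Cy5. Over the 3 sets, limma called 0 features for a dye effect, with 2630 at an unadjusted p below 0.05 and a median size of 0.088. Without set numbers, the 6 arrays gave 554 calls, 339 higher and 215 lower in Cy5. Ctsk, the gene of the protease cathepsin K, was at -0.92 with treated RNA in Cy5 and 1.09 with it in Cy3, so that its mean was 0.083 ± 0.079 (adjusted p = 0.25). Among the features called for treatment, 189 had a dye effect larger than the treatment effect, which the average over both orientations removes.

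**Figure D3:**
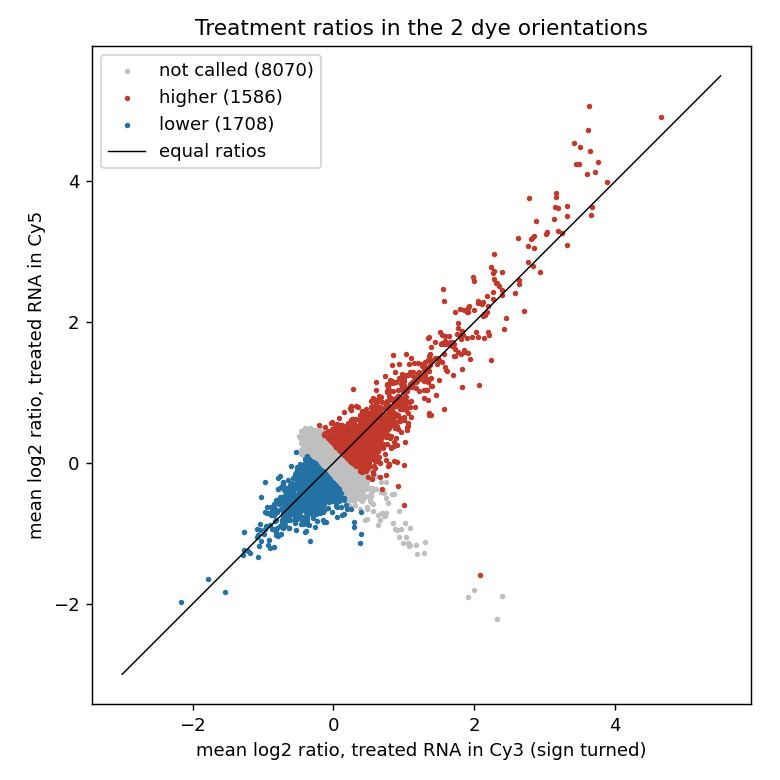
Each point is 1 of 11364 features, with its mean log2 ratio of treated over untreated RNA on the arrays with treated RNA in Cy3 (x axis) and in Cy5 (y axis), n = 3 arrays each. Of the 3294 called features (1586 higher and 1708 lower), 189 have means of opposite sign in the 2 orientations, as does Ctsk at lower right, which was not called.

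Arrays of the same dye orientation mostly resembled each other more than arrays of opposite orientation, apart from the set 3 pair. Across genes, which are not independent, Pearson's r after turning ranged from 0.739 to 0.838 for arrays of the same orientation and from 0.397 (the set 2 pair) to 0.775 (the set 3 pair) for arrays of opposite orientation. Averaged over both orientations, sets correlated at 0.928 (1 and 2), 0.914 (1 and 3) and 0.905 (2 and 3).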

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

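The tests of the ratio sizes by orientation were chosen after the result was seen, as was the dye test without set numbers; the other tests in this part were set beforehand. Without set numbers, 554 features differed between the dye orientations in their treatment ratio (339 higher and 215 lower in Cy5, median size 0.25, 149 of them also called for treatment), against 0 in the test over sets (limma, with 2630 at an unadjusted p below 0.05). Tjp1, a tight junction gene named after its values were seen, was at -1.59 with treated RNA in Cy5 and 2.08 with it in Cy3. Its mean of 0.24 ± 0.17 was called (limma adjusted p = 0.0277), but not without set 2 (0.15, adjusted p = 0.119) or set 3 (0.27, adjusted p = 0.0783).

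Sets 1 and 2 differed in their dye ratios more than in their treatment ratios: the difference between them had an SD of 0.289 across probes for the dye ratio and 0.147 for the treatment ratio. Whether set numbers were crossed was not settled. The dye difference of the 2 probes of a gene correlated at 0.0380 over 1701 genes. The treatment difference between the same sets gave 0.177 and the treatment effect 0.812. A low value was to argue against crossing, but the wider spread of the dye difference lowers this correlation in either case, so it cannot decide. A deviation that follows the order of the probes may account for the larger dye difference. Over 11200 pairs of neighbouring probes of different genes, the dye difference between sets 1 and 2 correlated at 0.323. The treatment effect averaged over all sets correlated at 0.0200. The treatment difference between sets 1 and 2 was not computed for these pairs. The contrast therefore cannot show that the pattern is particular to the dye ratio. Whether the probe order reflects place on the slide stays open, and no biological explanation was tested.

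Induced genes had larger ratios with treated RNA in Cy5: of the 78 features that rose at least 4-fold, 59 did, with medians of 2.72 in Cy5 and 2.63 in Cy3. A wider scale of all ratios on those arrays could give this. The 153 features that fell at least 1.5-fold had a ratio of sizes of 1.04, close to the 1.035 of the risers. Both lie below the 1.1 set as the sign of a wider scale. Since the risers themselves did not reach that mark, it cannot decide. By set, the ratio was 1.12, 1.06 and 1.12 for the risers and 1.01, 1.14 and 1.05 for the fallen features. A higher floor of dim signals in Cy5 would give fallen genes smaller sizes there, whereas their ratio of sizes was above 1 in each set. In sets 1, 2 and 3, 78, 93 and 91 of the 153 were larger in Cy5. Sets 2 and 3 thus lean against a higher floor, and set 1 is close to even. The rule needed a sign test to pass in all 3 sets, which was not met. These explanations cannot be told apart without intensities, and no biological explanation was tested.

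Rises outnumbered falls among large changes, with 191 against 12 named genes at 2-fold or more, although similar numbers passed the test (1333 and 1449). A zero point set too low by 0.3 or more is argued against: the median of 87 genes of the ribosomal, respiration and proteasome lists was 0.045. The mark of 0.3 was set beforehand and was not derived from the counts of rises and falls. By list the medians were 0.055, -0.056 and 0.11. The argument assumes that these genes did not respond, whereas the proteasome list was itself called as shifted upward (camera adjusted p = 1.36e-04). The treatment itself and a compression of ratios near the detection limit stay open and may both contribute.

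Outside the features measured on all 6 arrays, 828 were measured in at least 2 sets, and 88 of these changed with treatment (47 higher and 41 lower, 73 named), a signal in data that the comparisons leave out. The largest rises among named genes, chosen after their values were seen, were the neutrophil attractant gene Cxcl2 (4.82 ± 0.37, SD over 2 sets) and Stat2 (2.36 ± 0.11), which carries the interferon signal.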

How the results depend on the processing

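Keeping exact zeros, using named genes alone, dropping set numbers in the dye test and estimating the correlation over 6 arrays were added after the data were seen. The 3294 calls became 2618 to 2943 without 1 set, of which 2475 to 2680 were shared, and 2945, 3181 and 3292 under scale, quantile and median normalization. Counts stayed within 1.5 times (2431 to 3847) under the other settings apart from those that follow. The totals tested differ: 3847 are single probes of 13415, and 2431, with exact zeros kept, are features of 13241, against 3294 of 11364. Keeping zeros thus gave fewer calls from more features. The filter on matching signs (2797 calls of 3153 tested) selects on the change itself and is no check of the count. Treated-in-Cy5 arrays alone gave 1825 (931 higher, 894 lower), and treated-in-Cy3 arrays alone 2382 with 1079 lower. An adjusted p below 0.01 gave 2127 (1063 lower). A test against 1.5-fold gave 296 (261 higher, 35 lower), fewer by construction, since small changes no longer count. Of these, 88.2% were higher against 48.1% of the 3294, which follows the excess of rises among large changes. Dye effects went from 0 to 554 with no replicate block and ranged from 0 to 6 without 1 set. Called lists went from 17 to 0 with an estimated correlation over 3 values and to 1 over 6 arrays, and ranged from 16 to 18 without 1 set, with fry at 23. With the set number as a random replicate block 3412 features were called (3058 shared), with a fixed block 3294 by construction, and with no replicate block 3147 (2945 shared). Set numbers do not pair the arrays by the rule used: deviations of same-numbered arrays, after turning, correlated at -0.484, -0.512 and -0.020, and no array deviated most like the array of its own number. As deposited (Cy5 over Cy3) these are 0.484, 0.512 and 0.020, so the numbers do tie the arrays of sets 1 and 2 in their dye ratios. Over these settings the values of 223 of the named genes stayed on their side of the threshold in 3875 cases, lost the call in 206 and gained it in 82. This tally overstates stability. Of the 3875, 223 come from the fixed block, the same by construction, and 144 from the filter on matching signs. The single-probe setting took each gene's probe with the smallest p, and the naming rule favoured large changes. In 31 of the 3875 cases a value called in neither fit had the opposite sign, 26 of them on 1 orientation alone. Among genes called in either fit, signs turned for Ctsk (-0.92) and Tjp1 (-1.59) on treated-in-Cy5 arrays alone, and for Cd22 (-0.0068), Dhcr7 (-0.23), H2-Eb1 (-0.029) and Rpl30 (-0.0056) on treated-in-Cy3 arrays alone; the cause was not tested. Of 10 splits of the 6 arrays only the real 1 gave as many genes (3147, the highest other 0) or lists (16, the highest other 13). These are too few splits for a share below 0.05. Each other split mixes treated-in-Cy5 and treated-in-Cy3 arrays on both sides, so the treatment effect inflates its residual spread. Its lack of called genes therefore gives no support. Signal over background was not given in the values used here, so its limit on dim genes is unknown.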

Other observations

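The genes, families and list contrasts in this part were chosen after their values were seen. Among lists that rose, some members with well-known roles fell on all 6 arrays. The antibody receptor gene Fcgr3 was at -0.59 ± 0.083, the lipid receptor gene Trem2 at -0.53 ± 0.093 and the growth factor receptor gene Csf1r at -0.30 ± 0.067, the last with an adjusted p of 0.0503 on the treated-in-Cy3 arrays alone. The flagellin receptor gene Tlr5 fell with Tlr4, to -0.61 ± 0.14, and the phosphatase gene Inpp5d (SHIP1) to -0.58 ± 0.043. Klf2 (-0.62 ± 0.092) and Klf4 (-0.47 ± 0.091), Krüppel-like transcription factor genes, fell while most immediate early genes that changed rose. Of 12 measured genes named Klf, 2 rose and 5 fell. Cxcl14 was the 1 gene of the chemokine list that fell (-0.50 ± 0.24), a call that ended with exact zeros kept as values (limma adjusted p = 0.0997). Ccl19, a chemokine gene outside that list, fell further, to -0.74 ± 0.023 (limma adjusted p = 1.55e-05).

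Of 158 families of genes that share a name stem, 11 were shifted by camera, and each had adjusted p = 0.997 with an estimated correlation. In the Ms4a family of membrane proteins, 6 of 12 genes rose and 0 fell (adjusted p = 0.00824), with Ms4a6c at 2.43 ± 0.14, Ms4a4c at 1.92 ± 0.15, Ms4a6d at 1.83 ± 0.067 and Ms4a4b at 1.16 ± 0.37. These genes are close relatives, so a probe of 1 can bind another's transcript. Interferon regulatory factor genes rose in 5 of 8 cases (adjusted p = 0.0104), Irf1 by 2.21 ± 0.22, Irf7 by 1.99 ± 0.36, Irf8 by 1.04 ± 0.032 and Irf9 by 0.97 ± 0.20, which are also members of the interferon-stimulated list. Annexin genes, of calcium-dependent membrane-binding proteins, rose in 5 of 11 cases (adjusted p = 0.0351), with Anxa3 at 0.80 ± 0.047, a call that ended on treated-in-Cy5 arrays alone (adjusted p = 0.0615). Genes named Cep, most of them of centrosome proteins, fell in 9 of 17 cases (adjusted p = 0.0228), Cep72 to -0.62 ± 0.077. The 9 include the opposite-strand RNA Cep83os (-0.19 ± 0.11), which was not called without set 3 (-0.12, adjusted p = 0.111) or on treated-in-Cy5 arrays alone (-0.047, adjusted p = 0.774). Genes named Rad, most of them of DNA repair, fell in 6 of 12 cases (adjusted p = 0.0324), Rad54l to -0.58 ± 0.047.

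That interferon-stimulated genes rose more than cytokine, chemokine and NF-κB genes was tested by permuting genes between the lists. The medians were 2.30 over 37 genes and 0.84 over 55, a difference of 1.46 (two-sided permutation p = 0.00049 over 100000 draws). Because the contrast was picked after the medians were seen, this p does not exclude chance membership of the lists. Genes are also not independent, and the lists were picked from known responders. A larger fall of S phase than of mitosis genes was not shown by the same test: medians of -0.35 over 35 genes and -0.26 over 31 gave a two-sided permutation p = 0.185.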
